A study of Arabidopsis thaliana with 4 samples.

How the data were processed

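Total RNA from the aerial parts of 2-week-old Arabidopsis thaliana plants was hybridised to 4 arrays, 2 of Columbia control plants and 2 of jaw-D plants, an activation-tagged line. The deposited values are positive microarray intensities on a linear scale, 1 per probe set and array, for 22810 probe sets. The mean of the deposited intensities after trimming 2% at each end was 2500 on every array, so the arrays had been brought to a common level before deposit; the software and its settings are not given in the sources used here. The medians of the deposited intensities were 1069 and 1032 on the control arrays and 1139 and 1146 on the jaw-D arrays. No detection calls were used, and the number of arrays limits the precision of every value below.

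Several choices were made before the data were examined: the groups, the test, the pseudocount rule, the normalization rule, 26 gene lists, the rule for naming genes and the alternative settings. Under the normalization rule, arrays whose medians differed by over 10% were to be quantile normalised, and the highest median exceeded the lowest by 11.0%. The 64 control probe sets of the array were left out, and the 22746 others were quantile normalised between the 4 arrays. Values were then taken as log2(value + pseudocount), with a pseudocount of 302.3 units, the 25th percentile of all deposited values. Differences and folds on this scale understate the change of dim probe sets. Each probe set was tested for jaw-D against control with limma (version 3.58.1, lmFit, eBayes with a mean-variance trend, R version 4.3.3) and adjusted by Benjamini-Hochberg over all probe sets tested, with an adjusted p under 0.05 as the threshold. Unless another setting or an adjustment over a list alone is named, every adjusted p for a gene comes from this limma fit. It has 2 residual degrees of freedom per probe set, and all tests were two-sided. Nothing in the labels says that the 2 samples of a group came from separate plants or cultures, so p-values measure only the spread between these samples, which may be technical.

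Probe sets were named from the platform annotation, updated through gene identifiers to the reference gene table of the TAIR10.1 assembly, which was used only for names and for the order of neighbouring genes. Of the 22746 probe sets, 13513 had 1 gene, 503 had several genes and 8730 were unnamed here. The reference table matched 13436 of those with 1 gene, and 1580 of these 13513 carried a symbol other than a locus name. No gene was named from a probe set with several genes. Genes absent from this naming, among them most well-studied regulators, were not analysed here by name.

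The genes named were the 10 largest rises and the 10 largest falls among called probe sets with 1 gene and a symbol, where the jaw-D values both lay outside the control values; the measured genes next to MIR319A; and up to 4 members of each list with the smallest p. Genes named outside this rule are said to have been chosen after their values were seen. Of 326 entries in the 26 lists, 44 had a named probe set, and 7 of these lists had the 3 measured members that a test needed. For this reason 34 further lists were assembled from the gene names of the annotation, after the annotation and array-level summaries had been seen and before any difference between groups was computed. Their members were picked by symbol, and 2 were misplaced, which was seen after the tests: FRO1 (AT5G67590) in the iron list is FROSTBITE1, not ferric reduction oxidase 1, and ATCRT1 (AT5G56340) in the unfolded protein list is not calreticulin 1. The lists were left as first written. The 41 lists with enough members were tested with camera of limma (preset inter-gene correlation 0.01, with the variance trend) and adjusted together. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera draws its p from the 2 residual degrees of freedom, which leaves little power over 41 lists. No list had an adjusted p below 0.963 there, so missing this threshold says little about a list. A gene with several probe sets was represented by the one with the highest mean. The 27 probe sets for Bacillus subtilis transcripts reached at most 353 deposited units on any array, and a gene whose group means both lie at or under this level is called near background.

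The test was checked on simulated arrays with the levels of these 22746 probe sets and independent noise. The spread was drawn around a trend of the measured spread that was scaled up. Only the planted probe sets, all above the 40th percentile of mean level, were changed, far fewer than the 952 called in the data. The simulated counts therefore do not measure the sensitivity of the real fit. With 2 arrays per group the test called 58 of 66 probe sets changed by 2 on the log2 scale, 11 of 67 changed by 1 and 0 of 67 changed by 0.5, with 3 false calls. With 1 control array left out it called 0 of 66, 0 of 67 and 0 of 67. In a single simulation of 21 lists of 25 probe sets with independent noise, the lowered list was called by camera with the preset correlation. It was missed with an estimated one. The planted fall was close to the median fall of the nuclear photosynthesis list given below. No list of correlated genes was simulated, so this result does not favour the preset correlation over the estimated one. Alternatives to the normalization, pseudocount, filter, variance model, replicate block and number of arrays were run, and the closing section gives their effect.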

Results

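Transcript levels were measured in the aerial parts of 2-week-old Arabidopsis plants, with 2 arrays of Columbia controls and 2 arrays of jaw-D. The jaw-D line is a dominant activation-tagged mutant with uneven, crinkled leaves, in which enhancers of the tag raise the microRNA miR319a (miR-JAW). This microRNA pairs with transcripts of a group of TCP transcription factors that restrain leaf growth. The arrays answer which transcripts differ between such plants and the control, and the study used them to look for transcripts lowered by the microRNA. After quantile normalization, log2 values correlated across probe sets at 0.990 between the control arrays, at 0.992 between the jaw-D arrays and at 0.980 to 0.984 between groups.

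The largest fall among genes with a symbol was that of RR16 (AT2G40670, also called ARR16), a type-A response regulator of cytokinin signalling. Its intensity fell from 5604 ± 365 in control to 962 ± 55.3 in jaw-D (SD, n = 2 each), a log2 difference of -2.22 ± 0.10 (SE) and an adjusted p of 0.00209. The light-harvesting antenna gene LHCB4.3 fell from 21925 ± 1906 to 7892 ± 134 units, and the sucrose-phosphate synthase gene ATSPS4F from 3199 ± 50.2 to 999 ± 184. Among the rises, PYK10, the beta-glucosidase of endoplasmic reticulum bodies, went from 11603 ± 1053 to 28136 ± 3836 units. It rose together with 3 jacalin-related lectin genes, JAL22, JAL33 and JAL34.

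In all, 374 probe sets were higher and 578 lower in jaw-D, and 30 of the first and 91 of the second differed by over 1 on the log2 scale. At an unadjusted p under 0.05 there were 4523 probe sets, against 1137 expected by chance. Of the 952 called probe sets, 94 carried a gene symbol, 395 a locus name only, 12 several genes, and 451 were unnamed here. Higher probe sets made up 39.3% of the calls, and 17.9% when each array was centred on its own median instead. In limma, no higher probe set was called with any 1 array left out (1641 to 2216 at an unadjusted p under 0.05), and lower calls numbered 0 without control 1 or control 2, 13 without jaw-D 1 and 14 without jaw-D 2 (1698 to 2166 unadjusted); without the variance trend 14 were higher and 51 lower. Of 43 named genes that passed, 9 also passed without the variance trend: CP1, SP1L2, JAL34, RR16, LHCB4.3, ATSPS4F, MSRB6, UGT76E11 and AT4G23720.

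**Figure D1:**
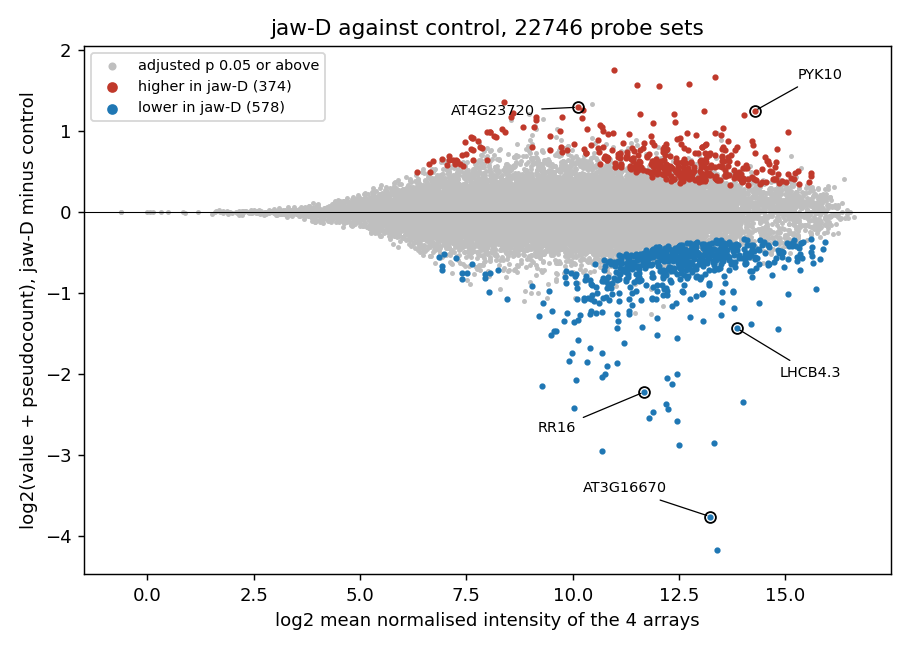
Log2 difference of jaw-D minus control (y axis, log2(value + pseudocount)) against the log2 mean normalised intensity of the 4 arrays (x axis) for the probe sets tested. Red points are the 374 probe sets higher and blue points the 578 lower in jaw-D at an adjusted p under 0.05; RR16 lies at -2.22 and PYK10 at 1.25.

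Among genes with a symbol, the largest of the 10 largest rises was that of CP1, a papain-type cysteine proteinase. It went from 583 ± 20.4 to 1829 ± 9.3 units (log2 difference 1.27, adjusted p 0.0176). The order of the rises depended on the pseudocount. At 4 times its value CP1 rose by 0.762 and PYK10 by 1.192, and at 0.1 times CP1 rose by 1.6 and MYBC1 by 1.608. At the main pseudocount the next rises were as follows. PYK10 rose by a log2 difference of 1.25 (adjusted p 0.0155), MYBC1, a MYB-related transcription factor, by 1.17 (adjusted p 0.0299), and SP1L2, a relative of the microtubule protein SPIRAL1, by 1.16 (adjusted p 0.0196). The lectin genes JAL34, JAL22 and JAL33 rose by 0.96 to 1.12, with adjusted p between 0.0107 and 0.0275. Cell wall genes among the 10 were TBL36, of a family of polysaccharide acetyltransferases (2426 ± 663 to 4858 ± 29.1 units, 0.94; adjusted p 0.0436, and 0.053 with each array centred on its median), and the endoglucanase gene GH9B13 (6260 ± 6.9 to 11403 ± 330 units, 0.83). The auxin-conjugating enzyme gene GH3.17 rose from 1042 ± 115 to 2031 ± 331 units (0.79, adjusted p 0.049, and 0.0629 with the pseudocount at 4 times its value).

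Among genes with a symbol, the falls after RR16 were led by LHCB4.3 (log2 difference -1.44, adjusted p 0.00517) and ATSPS4F (-1.44, adjusted p 0.0155). Several genes with a locus name only fell further than RR16 and are given under the other observations. MSRB6, a methionine sulfoxide reductase gene, fell from 4735 ± 167 to 1583 ± 150 units (-1.42, adjusted p 0.0082). The lectin gene JAL23 fell from 2223 ± 269 to 767 ± 144 units (-1.24), while its neighbour JAL22 rose. CCS, the copper chaperone of superoxide dismutase, fell from 9413 ± 417 to 4346 ± 992 units (-1.08), and the glucosyltransferase gene UGT76E11 from 1595 ± 109 to 595 ± 1.7 (-1.08). NdhL, a subunit of the chloroplast NDH complex, fell from 11380 ± 329 to 5516 ± 841 units (-1.01). The plastid assembly factor gene CCB3 fell from 3523 ± 159 to 1719 ± 269 units (-0.93), and the carboxypeptidase-like gene scpl46 from 2052 ± 308 to 940 ± 107 (-0.92). The 10 falls had adjusted p between 0.00209 and 0.0347.

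**Figure D2:**
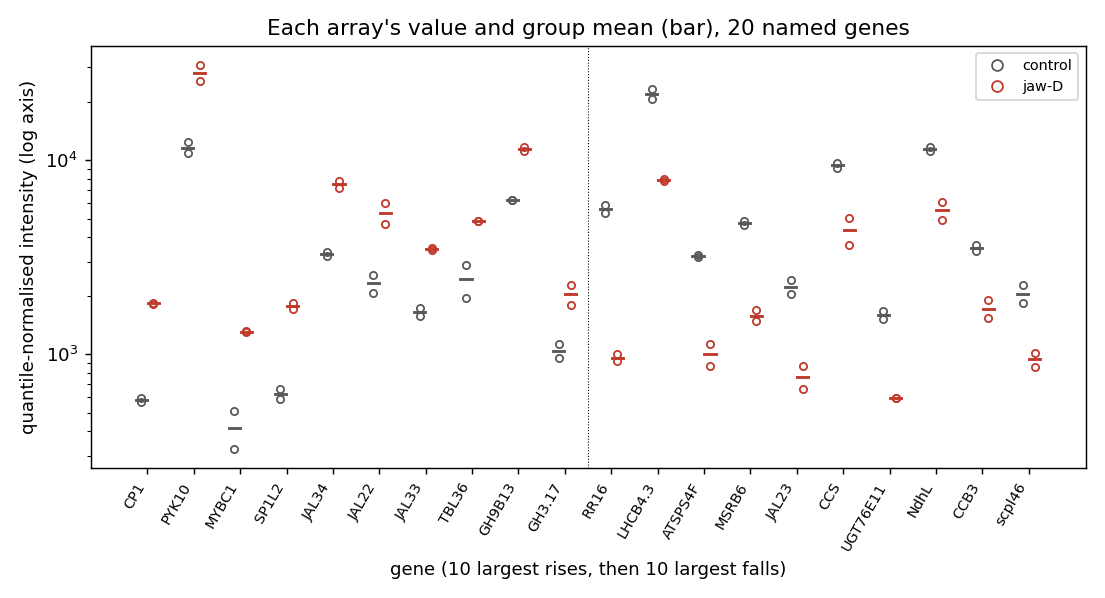
Quantile-normalised intensity (y axis, log scale) of the 10 largest rises and the 10 largest falls among called genes with a symbol (x axis) on each of the 4 arrays. Circles are arrays, grey for control and red for jaw-D, and bars are group means. In all 20 genes both jaw-D circles lie on 1 side of both control circles, which the naming rule required, as for RR16 at 962 units in jaw-D and 5604 in control.

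RR16 belongs to the genes reported downstream of the TCP class that miR319 targets. None of the 5 miR319-target TCP genes had a named probe set, so their level was not analysed here. Of genes reported downstream of this TCP class, 1 of 7 could be named, RR16, which fell as given above. As RR16 is the only measured member, adjusting over the list alone leaves its p unchanged and adds no support. The other measured type-A regulator, ARR15, was at 3036 ± 366 units in control and 3208 ± 150 in jaw-D (log2 difference 0.08, adjusted p 0.774), so that 1 of 2 in the cytokinin response list passed either way. Of the class I TCP genes, 2 of 13 could be named. TCP15 was at 2971 ± 287 and 4073 ± 306 units (0.42, adjusted p 0.0917), 1 of 2 adjusted over the list alone, and TCP11 (AT2G37000) was near background.

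Among 7 measured genes with locus numbers beside MIR319A (AT4G23713), AT4G23720, the next named locus, rose from 520 ± 93.7 to 1714 ± 95.3 units. Its log2 difference was 1.298 ± 0.145 (SE), with an adjusted p of 0.0196 over all probe sets and 9.69e-04 adjusted over the list alone. The difference of AT4G23720 was 1.675 with the pseudocount at 0.1 times and 0.758 at 4 times the main setting. With 1 array left out its difference stayed between 1.18 and 1.42 but its adjusted p over all probe sets was 0.121 to 0.18. The other 6 genes did not pass either way. AT4G23670 was at 16614 and 18644 units in control and jaw-D (0.16), AT4G23680 at 402 and 473 (0.14), AT4G23730 at 2543 and 2959 (0.19) and AT4G23740 at 3229 and 2943 (-0.12). AT4G23760 and AT4G23780 were near background. Of 14 protein-coding loci in this stretch, the 7 others had no named probe set here.

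The list of nuclear genes for photosynthesis passed camera with the preset correlation (adjusted p of 1.03e-14). With an estimated correlation, where no list passed, camera gave p = 0.0274 and an adjusted p of 0.963. By fry the adjusted p was 0.0457. Of 25 measured genes, 11 fell, 0 rose and 14 did not pass the test, all 25 differences were negative, and 18 fell when adjusted over the list alone; 12 passed as deposited and 17 centred on the median. The median log2 difference was -0.36. Besides LHCB4.3 and NdhL, these included NdhN, another NDH subunit (13559 ± 942 to 8172 ± 76.8 units, -0.71), and PIFI, a factor required for NDH activity (20705 ± 255 to 13323 ± 743 units, -0.63). The list fixed before the data were examined had only 2 nameable members, LHCB4.1 at 79086 and 71210 units (-0.15, adjusted p 0.317) and RCA, rubisco activase, at 69442 and 67365 (-0.04, adjusted p 0.843). Of 69 genes encoded by the plastid genome, atpH rose (0.41) and rpl33 fell (-0.56), the others did not pass, and the camera adjusted p was 0.472 with a median of -0.05. The atpH call ended in both other scalings (0.32, adjusted p 0.0889 as deposited, and 0.20, adjusted p 0.215 centred on the median), and 4 of the 69 passed centred on the median. The plastid list had a median of -0.12 as deposited and -0.22 with each array centred on its median. As deposited its camera adjusted p was 5.19e-05 with the preset correlation. With an estimated correlation, run on the quantile-normalised values alone, camera gave a p of 0.511 and an adjusted p of 0.997.

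In the auxin response list, 2 of 7 measured genes rose, 0 fell and 5 did not pass, while 4 rose when adjusted over the list alone. WES1 (also GH3.5), an auxin-conjugating enzyme, rose from 1582 ± 64.4 to 2811 ± 315 units (log2 difference 0.72), and the homeobox gene HAT2 from 2328 ± 33.3 to 3523 ± 227 (0.54). GH3.3 was at 1732 and 2801 units (0.62, adjusted p 0.0625, and 0.0423 as deposited) and IAA30 at 358 and 681 (0.57, adjusted p 0.0878). The list's median was 0.54, with a camera adjusted p of 0.0813, and 0.963 with an estimated correlation. In the wider list of auxin signalling, conjugation and synthesis, 3 of 20 rose, WES1, HAT2 and GH3.17, and 0 fell (camera adjusted p 0.136). Without the variance trend these 3 did not pass (adjusted p 0.0811 to 0.0919).

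Of 18 expansins, wall-loosening proteins, EXPB3 (5070 ± 129 to 7897 ± 234 units, 0.61), EXPA15 (0.69) and EXPA4 (0.50) rose and none fell, against a camera adjusted p of 0.29; as deposited EXLA2 passed too (adjusted p 0.0496). TBL38 (0.67) and TBL36 rose among 22 TBL genes (0.29), GH9B13 among 15 GH9 endoglucanases (0.662), and none of 10 XTH genes passed (0.622), the values in brackets after the families being camera adjusted p. Of 29 serine carboxypeptidase-like genes, scpl25 (0.71), scpl35 (0.55; adjusted p 0.0217, and 0.0825 centred on the median) and SCPL45 (0.57) rose and scpl46 fell; fry gave this list an adjusted p of 0.0457 and camera 0.472. The vacuolar processing protease gene GAMMA-VPE rose from 8531 ± 736 to 14871 ± 960 units (0.78, adjusted p 0.0198), the member of 7 in its list that passed. In the list of lateral organ growth and shape, 1 of 15 genes passed: NGA2, a NGATHA transcription factor, fell from 1440 ± 35.1 to 722 ± 77.1 units (-0.77, adjusted p 0.0399). The list's median was -0.06, while camera's direction was up (adjusted p 0.997). JAG, which promotes organ growth, was at 370 and 707 units (0.59, adjusted p 0.144), and AN at 3076 and 4336 (0.46, adjusted p 0.0569, and 0.039 as deposited).

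Among jasmonate genes, JMT, which methylates jasmonic acid, passed the test (adjusted p 0.0275). It was lower in jaw-D, at 298 ± 46.3 units in control and 37.0 ± 21.4 in jaw-D, but both are near background and the log2 difference was set by the pseudocount, from -2.32 at 0.1 times to -0.27 at 4 times its value, so no size is given. OPCL1, of jasmonate synthesis, was at 3094 and 2243 units (-0.42, adjusted p 0.0922), and both passed adjusted over the list alone. The defensin genes PDF1.2 (1084 and 473 units, -0.83, adjusted p 0.0675) and PDF1.2b (1591 and 817, -0.74, adjusted p 0.17) and the thionin gene THI2.1 (556 and 331, -0.46, adjusted p 0.332) did not pass. Adjusted over the list alone, 2 of these 3 fell, PDF1.2 and PDF1.2b. The PDF1.2b probe set ends in _x_at, a mark of probes shared with similar transcripts, so the 2 falls may not be independent. For the list of these 3 genes the camera adjusted p was 0.0813, and 0.963 with an estimated correlation. For the wider list of 10 jasmonate genes, where JMT was the member that passed, it was 0.29. In this list 4 differences were positive and 6 not, MYC4, a transcription factor of jasmonate signalling, was at 1292 and 1881 units (0.45, adjusted p 0.0846), and 1 rose and 4 fell adjusted over the list alone.

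UGT78D2, a flavonoid glucosyltransferase, fell from 2948 ± 80.6 to 1938 ± 128 units (-0.54, adjusted p 0.0444, and 0.052 as deposited and 0.0534 with the pseudocount at 4 times its value), 1 of 7 flavonoid and anthocyanin genes (camera adjusted p 0.072). In the flavonoid list fixed before the data were examined, DFR was at 1937 and 1331 units (-0.46, adjusted p 0.114) and fell adjusted over the list alone, and UF3GT and AT5MAT did not pass (camera adjusted p 0.29). Of 47 UGT genes 3 fell, UGT76E11, UGT84A3 (-0.76) and UGT78D2, and 0 rose (camera adjusted p 0.685). Of 14 glutathione transferase genes GSTU18 (-0.60) and GSTU20 (-0.56) fell (0.225), and centred on the median 4 passed. The vacuolar sugar transporter gene SWEET2 fell from 2201 ± 8.1 to 1094 ± 249 units (-0.85), 1 of 14 SWEET genes (0.997). Among 6 glucosinolate genes none passed (0.136), with BCAT4 at 6226 and 3645 units (-0.74, adjusted p 0.0535), but BCAT4 passed as deposited (adjusted p 0.0449) and BCAT4 and GTR1 passed centred on the median (0.0339 and 0.0331). PYK10 was the member that passed among 21 BGLU glucosidases (0.997), and none of 19 CYP71B genes passed (0.997).

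**Figure D3:**
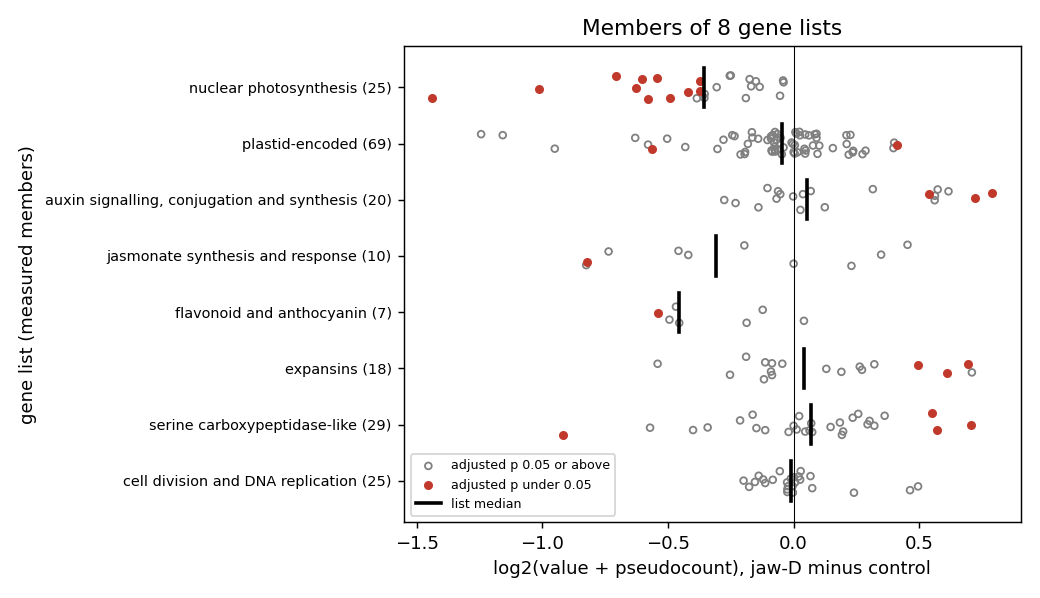
Log2 difference of jaw-D minus control (x axis, log2(value + pseudocount)) of each measured member of 8 gene lists (y axis); filled red circles passed an adjusted p of 0.05, open grey circles did not, and black bars are list medians. All 25 nuclear photosynthesis genes lie below 0 with a median of -0.36, and 0 of 25 cell division genes passed.

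None of 25 measured genes of cell division and DNA replication passed (camera adjusted p 0.997), with 0 adjusted over the list alone; as deposited 1 passed, TOPII, a topoisomerase gene (0.54, adjusted p 0.0408, against 0.059 here). In the cell cycle list, AUR1 (4622 and 4521 units), AUR2 (2523 and 2478) and PRL, also MCM7 (3455 and 3436), differed by at most 0.03. The polarity genes PHV (2734 and 3247 units, 0.23), YAB3 (-0.07) and YAB5 (-0.06) did not pass, and neither did LAS (735 and 593 units, -0.21) or CLV3, near background, of the boundary and meristem list. Adjusted over the list alone, 0 members of these 3 lists passed. Camera gave adjusted p of 0.997 for the cell cycle and the polarity lists, the latter with a median of -0.06 and a direction of up. Among stomatal genes STOMAGEN was at 7560 and 5589 units (-0.42, adjusted p 0.0826, and 0.033 centred on the median), and among trichome genes GIS was at 1732 and 1021 (-0.62, adjusted p 0.0548, and 0.0493 centred on the median); the lists' camera adjusted p were 0.472 and 0.997.

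Flowering, clock, stress and senescence genes gave 1 further call. DI21, a drought-induced gene, rose from 9275 ± 135 to 13930 ± 1641 units (0.57, adjusted p 0.0378, and 0.0807 centred on the median), 1 of 13 cold and dehydration genes (camera adjusted p 0.29), of which 2 others passed as deposited: COR15B, higher in jaw-D at 2889 and 5277 units (adjusted p 0.0381), and LEA4-5, lower and near background (adjusted p 0.0479, and 0.0409 centred on the median). GI, of the clock and of flowering, was at 2250 and 2840 units (0.30, adjusted p 0.142), and COR27 at 5239 and 7102 (0.42, adjusted p 0.0755). AGL24 was at 2136 and 1982 units (-0.09) and the heat shock gene ATHSP22.0 at 645 and 610 (-0.05). STZ was at 3997 and 5033 units (0.31, adjusted p 0.09) and COR15A at 540 and 722 (0.28). GI and STZ passed when adjusted over their lists of 1 or 2 members alone, and 0 members of the photosynthesis, heat shock and senescence lists fixed before the data were examined did. The senescence regulators WRKY6 and WRKY53 differed by 0.17 and -0.01, and SAG29 was near background (camera adjusted p 0.858). No member passed in the lists of clock-associated genes (camera adjusted p 0.29), floral transition (0.997), rapid wound and elicitor response (0.997), heat shock and chaperones (0.997), unfolded protein response (0.997), ATG8 autophagy genes (0.997), iron homeostasis (0.997) and tetraspanins (0.472). The iron list also held FRO1 (AT5G67590, FROSTBITE1), which is not the ferric reductase of that symbol; it was the member that passed centred on the median (-0.465, adjusted p 0.0311).

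Markers of other tissues were examined beside these groups. Of 6 root-expressed markers PYK10 rose and the 5 others did not pass, with EXPA18 at 572 and 433 units (-0.25, adjusted p 0.424) and EXPA7 near background (camera adjusted p 0.997, and 0.728 for the 3 root markers fixed earlier, of which 1, PYK10, passed adjusted over the list alone). None passed among 9 pollen markers (0.997), 4 egg cell and ovule markers (0.997) and 4 seed markers (0.728). Of the reference genes, PEX4 (also UBC21) was at 6268 and 6105 units (-0.03) and TIP41 (AT4G34270) at 3514 and 3135 (-0.14). No member could be named of the lists for GAMYB-like MYB, GRF, other microRNA targets, class II TCP without a miR319 site, salicylate and defence, floral organ markers and seed storage.

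The ratios of 3' to 5' control probe sets overlapped between the groups. Ratios of 3' to 5' probe sets were 6.97 and 7.34 in control and 6.21 and 7.78 in jaw-D for actin, and 1.92 and 1.63 against 1.49 and 2.08 for GAPDH. For ubiquitin they were 3.4 and 2.73 in control and 2.64 and 3.48 in jaw-D. All exceeded 1, and their overlap does not show that the RNA was intact. Between 26.4% and 29.6% of probe sets lay below the highest bacterial control on each array.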

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

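All alternatives were planned. None of 43 named genes that passed changed direction in any of 12 settings (42 genes under the filter). Of these calls, 41 held with values as deposited, 39 with each array centred on its median, 43 and 41 with the pseudocount at 0.1 and 4 times its value, 42 of 42 under the filter, 43 with a robust fit, 9 without a variance trend, 32 with the replicate block, and 0, 0, 1 and 1 without control 1, control 2, jaw-D 1 or jaw-D 2. The counts higher and lower (374 and 578) became 215 and 983 with centring on the median, 1030 and 1199 above the 40th percentile of mean level (fewer probe sets tested, 331 and 554 shared), 14 and 51 without a variance trend, and 1 and 25 tested against a log2 difference of 0.5. Nearly all calls were lost with any 1 array left out. Such fits leave 1 residual degree of freedom and assume that the lone array varies like the other group. The simulated 3-array fits left out control 1 alone, with a spread and a share of changed probe sets unlike these data. They cannot tell whether the fewer degrees of freedom alone account for the lost calls. Same-numbered arrays did not deviate together (correlation across probe sets -0.021). This shows no shared effect of the number, but the labels do not say whether the numbers pair samples. With the replicate block 157 were higher and 309 lower. WES1, HAT2, GH3.17, NGA2, UGT78D2, UGT84A3, EXPA4, SWEET2, GSTU18, SCPL45 and atpH then did not pass (limma adjusted p 0.051 to 0.0804). The other settings, without probe sets ending in _s_at or _x_at included, stayed within 1.5 times. The 1 list past camera became 0 with an estimated correlation, 2 as deposited (plastid-encoded genes joined) and 2 with the replicate block (flavonoid and anthocyanin genes joined), and 1 by ranks. Of the genes beside MIR319A, 1, AT4G23720, passed as deposited and with the replicate block, and over all probe sets it did not pass with any 1 array left out (adjusted p 0.121 to 0.18); AT4G23670 turned to -0.046 (centred) and AT4G23760 to -0.026 (centred) and -0.002 (pseudocount 4 times); with 1 array left out AT4G23760 ranged from -0.24 to 0.26 and AT4G23780 from -0.34 to 0.089. The causes were not tested except where stated. The miR319-target TCP alternatives were not run, as no member was named. Signal over background limits genes near 353 units.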

Other observations

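The tests of the scalings, of an equal dilution of green tissue and of the 6 other neighbours of MIR319A were chosen after their results had been seen at least in part, and those of matched random lists, root peroxidases and windows before. The 5 probe sets with 1 gene and the smallest p, chosen after their values were seen, all fell and all belong to genes with a locus name only. AT3G16670 fell from 18168 ± 187 to 1060 ± 109 units (SD, n = 2 each), a log2 difference of -3.76 ± 0.09 (SE) with a limma adjusted p of 4.12e-04. AT3G05730 fell from 27644 ± 310 to 5211 ± 186 units (-2.34), AT2G29290 from 9886 ± 640 to 1398 ± 6.6 (-2.58), AT1G31690 from 6314 ± 95.4 to 829 ± 58.4 (-2.55) and AT5G18600 from 8112 ± 570 to 1327 ± 95.9 (-2.37).

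Genes of the endoplasmic reticulum body and the lectins that associate with PYK10 were grouped after their values were seen. Of 7 measured, PYK10, NAI2, JAL22, JAL33 and JAL34 rose and JAL23 fell. NAI2, a structural protein of these bodies, rose from 4049 ± 194 to 6095 ± 86.6 units (log2 difference 0.56, adjusted p 0.0275). NAI1, the transcription factor that drives several of these genes, was at 632 ± 44.4 and 788 ± 104 units (0.22, adjusted p 0.49). The smallest of the 5 rises was 0.465 over the 3 scalings, so the rises do not hinge on the choice among these. A bias common to all 3 scalings was not tested. PYK10 is abundant in roots, so root tissue in the jaw-D samples could also raise it. The median of 7 root peroxidase genes was 0.031, but all 7 were under the highest bacterial control in the control arrays and moved both ways, AT4G30170 from 62.4 ± 14.1 to 329 ± 106 units (adjusted p 0.0479) and AT3G01190 from 210 ± 59.7 to 51.6 ± 23.4 (adjusted p 0.0789). EXPA18 (572 and 433 units, -0.25) and LBD16 (627 and 587, -0.07), above that level, were no higher in jaw-D, which goes against root tissue. As these are 2 genes close to background and no root array gives the level to expect, root tissue and a change within the shoots of jaw-D cannot be told apart here.

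The nuclear photosynthesis list did not pass camera with an estimated correlation (adjusted p = 0.963), a test that no list passed. With the preset correlation its call rests on an assumed value, so what follows is about its measured differences. They do not follow from the brightness of their probe sets alone. Over 10000 random lists matched on mean level the medians centred on 0.037 and the lowest was -0.252, against -0.355 for the list. The random lists drew probe sets independently, so this speaks to brightness and gives no significance level for genes that vary together. The list's median was at most -0.355 over the 3 scalings, so its sign does not hinge on the choice among these. A bias common to all 3 scalings would not show in this comparison. An equal dilution of green tissue, acting alone, predicts like falls in all members. Among the 14 members below 30000 units the SD of the differences was 4.89 times their median SE. As this SE measures only the spread between these samples, the test cannot exclude a dilution with gene-specific changes on top of it. A shift in leaf age or growth stage at harvest in jaw-D may lower these genes unequally, and so might a change in the hour of harvest; neither was tested.

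AT4G23720 is the next named locus to MIR319A, and its rise is a candidate for a second gene reached by the enhancers of the tag. A rise as large occurred in 28 of 13187 windows of 7 measured neighbouring genes (0.212%). The windows overlap, and those that hold AT4G23720 itself are among the 28. The share therefore shows that few measured genes rose this far, and it does not measure chance. The smallest difference of AT4G23720 over the 3 scalings was 1.262, so its rise does not hinge on the choice among these. The 6 other measured neighbours had a median difference of 0.074, above 78.6% of windows of 6, which decides neither for nor against a wider reach. An effect of miR319a or of the changed growth of jaw-D on AT4G23720 stays open and was not tested.

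The control probe set for 25S ribosomal RNA read 48894 units on control 2, against 1015 on control 1, 1343 on jaw-D 1 and 1596 on jaw-D 2. The 5S ribosomal RNA probe set read 5525, 2086, 1675 and 1056 units on the same arrays in the order control 1, control 2, jaw-D 1, jaw-D 2.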
